A study of Homo sapiens with 8 samples.

How the data were processed

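Bulk RNA sequencing was done on 8 libraries of WTC11-derived cardiac progenitor cells on day 7, 4 transfected with siGATA4 and 4 with siNC. Per the labels' protocols, total RNA was extracted with a column kit and DNase digestion, and libraries were made with a low-input NuGEN kit. Reads were aligned with STAR 2.5.2a to hg19, per the submitters' processing notes. The deposited tables have the column layout of rMATS, a program that counts reads over the splice junctions of alternative events; its version and the strand setting are not given in the sources used here. The tables cover 5 event types: cassette exons, mutually exclusive exons, alternative 3′ splice sites, alternative 5′ splice sites and retained introns.

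Per the file headers, each event has junction counts for its inclusion and skipping forms, and each cell lists 4 libraries for sample 1 and 4 for sample 2. The headers name neither the treatment nor the library, so the sides are called arm 1 and arm 2 and no value was tied to siGATA4 or siNC. A mean ± SD is over the 4 libraries of a side. The inclusion level deposited for each library is the inclusion count over its effective length as a share of the sum of both forms; recomputed levels differed by at most 0.0005. The level difference, a score between the arms, was deposited by the authors as the mean level of arm 1 minus that of arm 2. The authors also deposited a p-value per event from their own comparison, equal to 1 in 78.5% of retained introns and in 89.4% of cassette exons, and for mutually exclusive exons a further p-value with its FDR. For mutually exclusive exons, inclusion refers to the form counted as inclusion in the deposited values. Effective lengths showed that only junction reads were counted.

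From these tables, 161 of 89886 events, on the Y chromosome or in the gene XIST, were removed, and 89725 remained. Events entered the test with a mean of at least 10 counts per library and at least 8 counts of the rarer form over the 8 libraries. For each event and library the log2 of (inclusion count + 0.5)/(skipping count + 0.5) was compared between arms with limma 3.58.1 in R 4.3.3, using weights from the counts, a variance trend on depth and robust moderation, with Benjamini-Hochberg adjustment within each event type and a threshold of 0.05. This differs from a count model, which had been set for tables with a column per library. A fold change here is on the log2 ratio scale with a pseudocount, which understates changes of rare forms. The depth of 21305022 to 33791438 listed counts per library sums counts over overlapping events, so a read can count more than once. Count filters, median depths of 96.8 counts per library for tested cassette exons and 62.5 for retained introns, and the spread between libraries set the precision.

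Gene abundance was approximated by the counts of the deepest event of each gene, for 8859 genes with a mean of at least 20 counts, scaled by the median ratio to the mean library over genes with a mean of at least 50 and tested with voom weights in limma. Genes with no listed event were not analysed here, and a change in the spliced form can move the abundance of an event. GATA4 was compared by a two-sided exact permutation test over 70 assignments. Lists of 13 gene groups were fixed before the data were examined. For changed splicing each was set against 10000 random lists matched on the number of events (7 classes) and depth (10 classes), and the permutation p-values were adjusted over the 13 lists. For abundance, calls were counted over all genes and adjusted over the list alone. Direction was tested with an exact binomial test with at most 1 event per gene, and frame by Fisher's exact test with each exon counted a single time.

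The genes named were set by a rule: up to 10 cassette exon genes per direction, 2 per direction for each other type, with an adjusted p under 0.05, a mean of at least 20 counts and levels that do not overlap between arms; up to 4 changed genes per list, or the best 1; and 6 genes per direction in abundance with a mean of at least 50 counts. Because few events passed, the same rule was also applied to the blocked fit, a choice made after the data were seen. Some genes that the rule or the lists take in are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

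The labels number the libraries 1 to 4 in each treatment, and the tables carry no numbers. Whether libraries at the same listed position deviate together was checked before the fits were compared. Over 2823 deep cassette exon events, same-position deviations from the arm means correlated at 0.217, 0.161, 0.124 and 0.155, and over 8859 genes at 0.255, 0.265, 0.335 and 0.280, across events and genes that are not independent replicates. Each was higher than with any other position, and all were above 0.1, so the position was fitted as a replicate block, an alternative added after the data were seen (49 cassette exon events against 6).

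Scripts were tested on simulated data with 200 changed features (188 for alternative 5′ splice sites). Of cassette exons changed by a log2 ratio of 1 the limma test recovered 8.5%, and of those changed by 2 it recovered 29.0%, among 17301 events. At 1 and 2 the shares were 56.5% and 85.0% for mutually exclusive exons (9591 events), 20.5% and 56.0% for alternative 3′ splice sites (2969), 10.6% and 52.7% for alternative 5′ splice sites (1889), 12.5% and 52.0% for retained introns (2512) and 67.5% and 96.5% for abundance (8859 genes). Alternatives were another count minimum or none, limma without weights, quasi-binomial regression, a pseudocount of 2, a minimum difference of 10 points, a single event per alternative, the authors' p-values, other scalings, sums over events, and leaving out each library. The tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Sequence motifs near exons were not analysed here, since no genome of the build of the coordinates was used.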

Results

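The series measured RNA splicing by bulk RNA sequencing in cardiac progenitor cells made from WTC11, an established human induced pluripotent stem cell line. Cells were differentiated by switching WNT signalling on with 6 µM of the activator CHIR for 48 h and off with 5 µM of the inhibitor IWP4 for 48 h. On day 5 they were transfected with an siRNA against GATA4, a zinc finger transcription factor of heart development, or with the control siRNA siNC. They were collected 48 h later, on day 7. Each treatment had 4 libraries, numbered 1 to 4, which are not said to come from separate cultures. The p-values here therefore speak only of these samples, whose spread may be technical. In limma, the spread of an event or gene is moderated by that of the others tested. A small p-value there does not rest on the 8 libraries alone. The values were junction read counts for 5 kinds of alternative splicing event, with 8 libraries in 2 arms of 4. The tables do not name the treatment of either arm. The arms are therefore called arm 1 and arm 2, differences are arm 1 minus arm 2, and no direction is assigned to the siRNA. The junction counts listed summed to 26852310, 21305022, 25741333 and 33791438 in the libraries of arm 1. They summed to 27523706, 23861229, 29270369 and 25700393 in those of arm 2.

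GATA4, the siRNA target, had fewer junction reads in every library of arm 2 than in any library of arm 1. Its most deeply covered event, a cassette exon on chromosome 8 from 11612555 to 11612642 (hg19), held 438, 331, 374 and 684 counts in arm 1 and 149, 88, 119 and 100 in arm 2. Scaled to the total of each library, GATA4 came to 16.7 ± 2.504 CPM in arm 1 and 4.27 ± 0.782 in arm 2 (SD, n = 4 each), a ratio of 3.91, with arm 2 at 25.6% of arm 1. The 4 arm 1 libraries had 16.3, 15.6, 14.5 and 20.3 CPM, and the 4 arm 2 libraries had 5.42, 3.69, 4.07 and 3.90. A two-sided exact permutation test over the 70 assignments of the libraries gave p = 0.0286, the smallest p this design can reach. Junction reads of alternative events stand in for the transcript level here and are not a full measure of it.

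**Figure D1:**
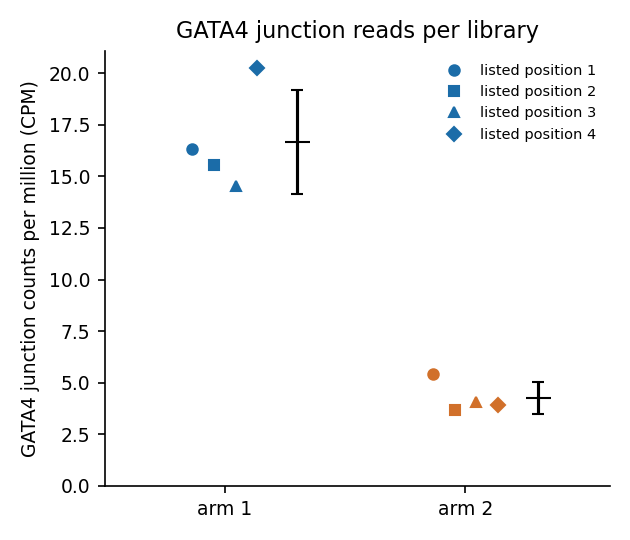
GATA4 junction CPM, counts scaled to the library total (y axis), in each of the 4 libraries of arm 1 and of arm 2, with marker shapes for the listed position and the black bar for the mean ± SD. The arm 1 libraries lie between 14.5 and 20.3 and the arm 2 libraries between 3.69 and 5.42.

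The comparison between the arms asked which splicing events change when GATA4 is depleted. The cassette exons that passed the test without a block were all included more in arm 1, the arm with more GATA4 reads. A 93-nucleotide exon of BIN1, a membrane-bending protein of the muscle T-tubule, had an inclusion level of 50.03% ± 4.88 in arm 1 and 30.6% ± 8.65 in arm 2 (SD, n = 4 each). A 140-nucleotide exon of EIF4A2, an RNA helicase of translation initiation, was included at 77.9% ± 0.810 in arm 1 and 62.1% ± 3.45 in arm 2. A 42-nucleotide exon of PTPRD, a receptor tyrosine phosphatase, stood at 36.8% ± 2.10 against 24.2% ± 4.38. ATPAF1, an assembly factor of the mitochondrial ATP synthase, included a 96-nucleotide exon at 92.1% ± 1.89 against 80.8% ± 8.12.

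Of 17301 cassette exon events tested in 6307 genes, 6 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment. All 6 were higher in arm 1, 4 of them by at least 10 percentage points. The EIF4A2 exon (chromosome 3, 186502751 to 186502890) had a log2 ratio of inclusion to skipping counts 1.10 ± 0.125 (SE) higher in arm 1, with a limma adjusted p of 1.52e-12. For BIN1 (chromosome 2, 127825739 to 127825831) the log2 difference was 1.11 ± 0.216, adjusted p = 0.00320, and for PTPRD (chromosome 9, 8437198 to 8437239) it was 0.85 ± 0.148, adjusted p = 0.000191. The ATPAF1 exon (chromosome 1, 47110833 to 47110928) differed by 1.57 ± 0.353, adjusted p = 0.0360. A 62-nucleotide exon of the apoptosis inhibitor API5 (chromosome 11, 43339971 to 43340032) was rare in both arms, at 5.92% ± 1.56 against 2.15% ± 0.311, with a log2 difference of 1.49 and adjusted p = 0.00320. The remaining call was an 84-nucleotide exon of the growth factor TGFB2 (chromosome 1, 218536676 to 218536759), at 12.3% ± 2.19 against 8.50% ± 1.30, log2 difference 0.60, adjusted p = 0.00320. Its levels overlapped between the arms, and it was named after its values were seen. In limma, 1405 events had an unadjusted p under 0.05. A quasi-binomial regression called 9 events, without ATPAF1 (adjusted p = 0.202), and limma called 0 without observation weights, 1 with a pseudocount of 2 and 1 without a count filter. Leaving out any single library raised the count to between 11 and 27. The ATPAF1 call was lost without library 1, 2 or 4 of arm 1 or library 1 of arm 2, where its adjusted p reached 0.252. The BIN1 call was lost without library 4 of arm 2, adjusted p = 0.0897.

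Splice site choice differed in 4 further genes. SLU7, a factor of the second step of splicing, used the longer of its alternative 5′ splice site forms at 8.85% ± 1.40 in arm 1 and 29.4% ± 3.29 in arm 2. This event had a mean of 36.5 counts per library. Its long form shares the end at 159845603 with a 90-nucleotide SLU7 cassette exon, so the same reads may count for both events. The long form of an alternative 3′ splice site event in ZNF462, a zinc finger protein, stood at 28.0% ± 3.28 in arm 1 and 19.3% ± 1.65 in arm 2, and that of WSB1, a substrate adaptor of a ubiquitin ligase, at 72.2% ± 4.18 and 62.5% ± 3.58. MYL7, the atrial myosin regulatory light chain, shifted by less, with the longer 3′ splice site form at 11.02% ± 0.519 against 12.6% ± 0.369 (SD, n = 4 each). These levels are corrected for the effective lengths of the forms.

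Among 2969 alternative 3′ splice site events, 3 passed in limma: MYL7 (chromosome 7, 44180311 to 44180426; log2 difference -0.23, adjusted p = 0.00903), ZNF462 (chromosome 9, 109694544 to 109694830; 0.75, adjusted p = 0.0137) and WSB1 (chromosome 17, 25634770 to 25636298; 0.68, adjusted p = 0.0424). Of 1889 alternative 5′ splice site events, 1 passed, in SLU7 (chromosome 5, 159845603 to 159846088; log2 difference -1.99, limma adjusted p = 0.0289). The quasi-binomial regression called 3 alternative 3′ splice site events, MYL7 (adjusted p = 0.0229) and ZNF462 (0.0348) among them but not WSB1 (0.0734), and 0 alternative 5′ splice site events (SLU7, 0.0937). In limma, 0 of 9591 mutually exclusive exon events and 0 of 2512 retained introns passed, with 446 and 117 at an unadjusted p under 0.05, and the quasi-binomial regression also called 0 of each. Limma without weights called 1 mutually exclusive exon event and 0 of each other kind, and without a count filter it called 0 alternative 3′ splice site events. Across the 5 kinds, 34262 events in 7951 genes were tested and 10 events in 10 genes passed. The SLU7 call was lost in 6 of the 8 fits that left out a library (all but those without library 1 or 2 of arm 2), with an adjusted p of up to 0.177. WSB1 lost its call without library 1 or 4 of arm 1 or library 1 or 3 of arm 2 (adjusted p up to 0.341), ZNF462 without library 4 of either arm (up to 0.330) and MYL7 without library 1 of arm 1 (0.0987). The number of alternative 3′ splice site events that passed was 1 without library 1 of arm 1, 5 without library 3 of arm 1 and 6 without library 2 of arm 2.

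**Figure D2:**
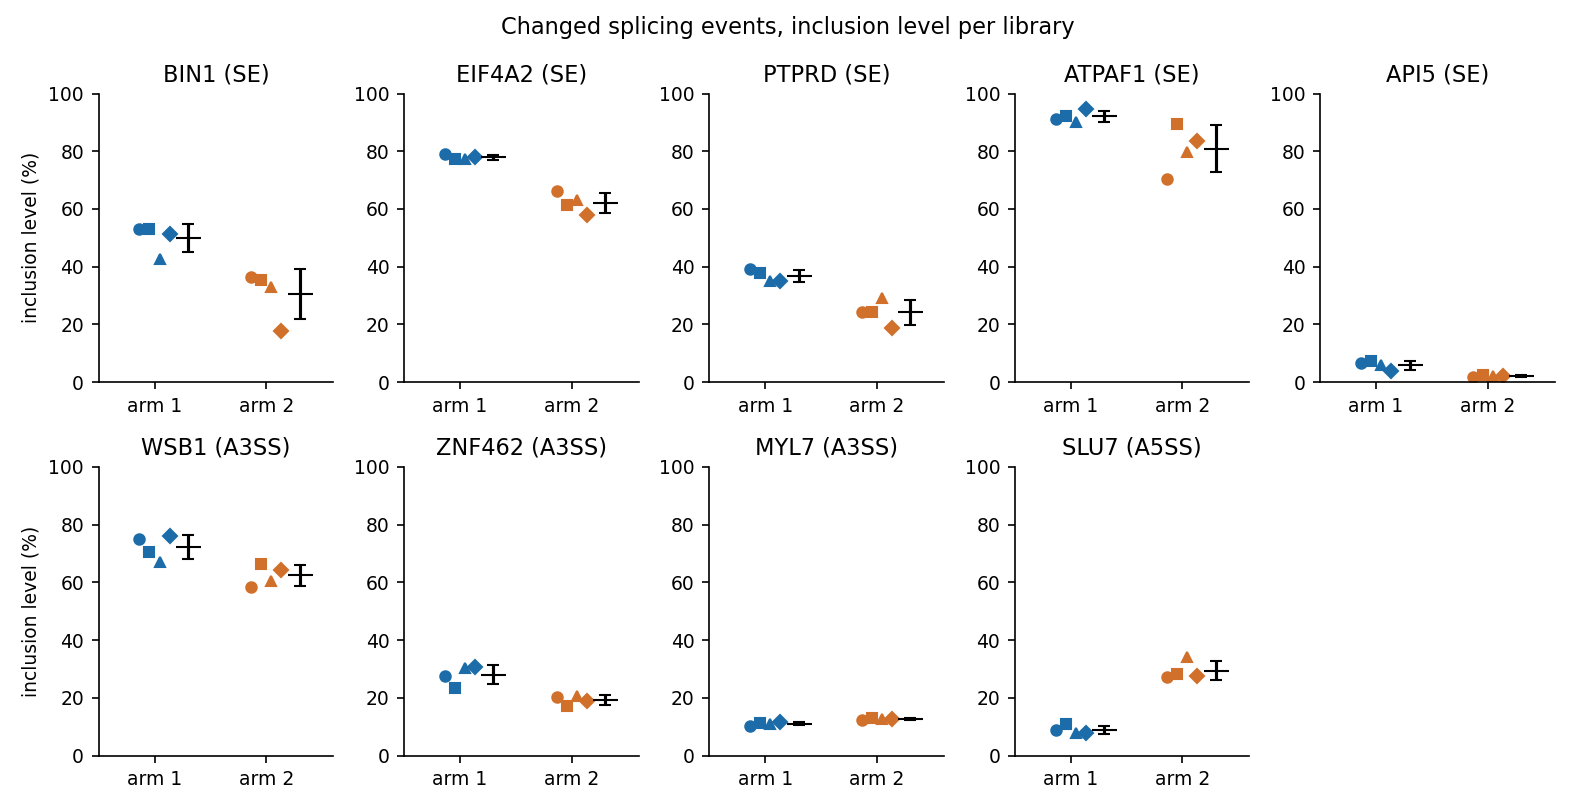
Inclusion level in percent (y axis) of 9 of the 10 events that passed, in each library of arm 1 (blue) and arm 2 (orange), with marker shapes for the listed position (circle 1, square 2, triangle 3, diamond 4) and the black bar for the mean ± SD. These 9 events were chosen for levels that do not overlap between the arms, from MYL7 at 11.02% against 12.6% to SLU7 at 8.85% against 29.4%.

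With the listed position of a library as a replicate block, more events passed, among them exons of heart muscle genes. A 192-nucleotide exon of NEXN, an actin-binding protein of the Z-disc (chromosome 1, 78383251 to 78383442), was included at 45.9% ± 4.37 in arm 1 and 33.9% ± 5.19 in arm 2. RBFOX2, a splicing regulator, included a 120-nucleotide exon at 24.3% ± 5.64 against 12.2% ± 1.49 (chromosome 22, 36232367 to 36232486). SLC8A1, the sodium-calcium exchanger, included a 107-nucleotide exon at 39.6% ± 6.62 against 27.6% ± 6.16, and ATP2B1, a calcium pump of the plasma membrane, a 154-nucleotide exon at 10.7% ± 1.36 against 6.38% ± 1.75. TAZ, which encodes the cardiolipin remodelling enzyme tafazzin, went the other way, with a 90-nucleotide exon at 16.5% ± 10.3 in arm 1 and 45.2% ± 7.87 in arm 2 (SD, n = 4 each).

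This pairing comes from the order in which the tables list the libraries, not from a label, and was chosen after the data were seen. The blocked counts were 49 cassette exon events (30 higher in arm 1 and 19 in arm 2), 9 mutually exclusive exon events, 4 alternative 3′ and 4 alternative 5′ splice site events and 2 retained introns. These were 68 events in 50 genes, among them all 10 that passed without the block. Blocked limma adjusted p-values were 1.27e-10 for NEXN (0.196 without the block), 0.0143 for RBFOX2 (0.0942), 5.02e-05 for SLC8A1 (0.268), 0.00266 for ATP2B1 (0.0684) and 0.0362 for TAZ (0.196). Without the block, the quasi-binomial regression called NEXN (adjusted p = 3.65e-05) and SLC8A1 (0.0423), and limma called NEXN in all 8 fits that left out a library (adjusted p up to 0.000152). Such fits called SLC8A1 in 5 of 8 (without library 2 or 4 of arm 1 or 1, 2 or 3 of arm 2), TRIP12 in 5, ATP2B1 in 3 and RBFOX2 and TAZ in 1 each. Exons of SEPT7 (89.9% against 64.0%), CCDC41 (69.7% against 43.6%), ZNF618 (32.1% against 14.8%) and TRIP12 (67.8% against 60.6%) were also included more in arm 1 in the blocked fit. Those of PCM1 (32.1% against 40.02%), ASPH (75.9% against 79.1%), SLC38A2 (98.5% against 99.4%) and SLU7 (6.67% against 27.7%) were included less. The SLU7 exon, with a mean of 34.9 counts per library, may share its reads with the SLU7 5′ splice site event above. Outside cassette exons, the blocked calls took in R3HDM1 with an alternative 5′ splice site (85.2% against 74.0%) and GCOM1 with mutually exclusive exons (36.0% against 16.6%), the latter uncertain because GCOM1 is a read-through locus whose exons overlap other genes. Swapping the arms within positions called up to 39 mutually exclusive exon events and up to 6 retained introns, more than the 9 and 2 of the real arms. Without the block, limma adjusted p-values of these 10 events, from SEPT7 on, ran from 0.0684 for SEPT7 to 0.324 for GCOM1, and the quasi-binomial regression called 0 of them. The fits without a library called SEPT7 and ASPH in 2 of 8, PCM1 and GCOM1 in 1, and CCDC41, ZNF618, SLC38A2, the SLU7 exon and R3HDM1 in 0. In simulated cassette exon data with log2 changes of 2, the blocked fit made 17.4% false calls among its calls. The quasi-binomial regression made 10.7% and limma without the block 1.7%. With log2 changes of 1 the blocked share was 8%, and those of the other 2 fits were 0%. The simulated libraries had no position effect, whereas deviations of the real ones correlated by position.

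Among the 13 gene lists fixed before the data were examined, sarcomere and contractile genes held the most blocked calls for their number, with 8 of 42 tested genes changed. TTN, the giant spring protein titin, included a 138-nucleotide exon (chromosome 2, 179654087 to 179654224) at 51.1% ± 5.09 in arm 1 and 43.5% ± 4.80 in arm 2. TNNT2, cardiac troponin T, included a 9-nucleotide exon at 3.48% ± 1.04 against 2.58% ± 0.613, and TPM1, alpha-tropomyosin, retained an intron at 12.5% ± 1.72 against 10.4% ± 1.82. NEBL, the Z-disc protein nebulette, included a 105-nucleotide exon at 40.2% ± 10.4 against 44.6% ± 10.2, and MYL6 and MYL7 were also lower in arm 1.

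In the blocked fit, random lists matched on the number and depth of events gave 1.32 changed genes on average for the sarcomere list. The permutation p was 0.0001, the smallest that 10000 random lists can give, and the adjusted p over the 13 lists was 0.0013. The deepest class used for matching had no upper limit. The blocked events of MYL6, MYL7, TPM1 and TNNT2 had means of 20240, 17240, 14153 and 9412 counts per library. A greater chance of a call at such depth may therefore remain. The list test was not repeated with the arms swapped within positions. Of the 8 genes, 5 were higher and 3 lower in arm 1. TTN, TNNT2 and MYL6 were named after their values were seen. Without the block limma called MYL7 in this list, 1 of 42 genes (expected 0.232, permutation p = 0.210), and the quasi-binomial regression called MYL7 and NEXN. That MYL7 call is the alternative 3′ splice site event above. The blocked MYL7 event of 17240 counts is an alternative 5′ splice site, at 8.65% against 9.575%. It did not pass without the block (limma adjusted p = 0.796). The differences of TTN, TNNT2, TPM1, MYL6 and NEBL did not then pass, with limma adjusted p from 0.694 for TTN to 0.993 for TPM1. TTN is overlapped by an antisense gene and the strand setting of the counting is not given in the sources used here, so its reads are uncertain. Calcium handling genes held 3 blocked calls of 28 (ASPH, ATP2B1 and SLC8A1; permutation adjusted p = 0.0552). Cytoskeleton and adhesion genes held 3 of 67 (ACTN4 and BIN1 among them; 0.663), splicing regulators 2 of 121 (HNRNPA2B1 and RBFOX2), chromatin regulators 1 of 83 (KDM3A) and mitochondrial genes 1 of 39 (SLC25A3). Without the block ACTN4, HNRNPA2B1, KDM3A and SLC25A3 had limma adjusted p-values from 0.204 for KDM3A to 0.802 for ACTN4. The cardiac transcription factor (39 tested), WNT, BMP and TGF-beta (47), pluripotent (7), endothelial (2), endoderm (8), smooth muscle and fibroblast (15) and neural (3) lists held 0 changed genes with or without the block. TGFB2, which passed without the block, is not a member of the WNT, BMP and TGF-beta list. In limma without the block BIN1 was the only changed gene of the cytoskeleton list (1 of 67), and 0 of the 13 lists passed under the random-list test, Fisher's exact test, or the authors' deposited p-values.

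**Figure D3:**
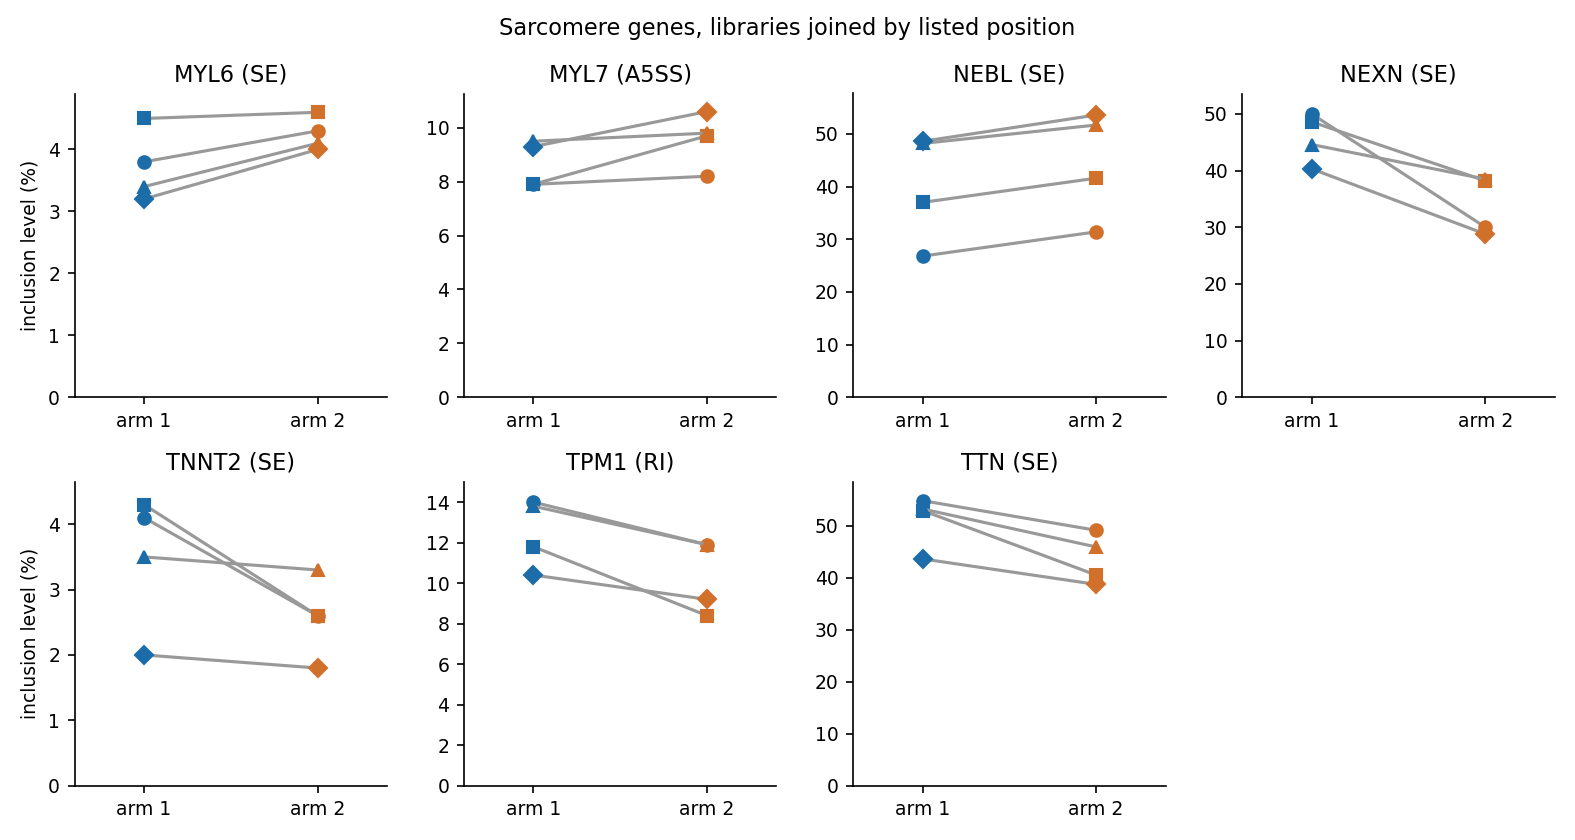
Inclusion level in percent (y axis, from 0) for the event with the smallest blocked p in each of 7 sarcomere genes, in arm 1 (blue) and arm 2 (orange), a choice that favours lines running the same way; each grey line joins the libraries at the same listed position (circle 1, square 2, triangle 3, diamond 4). All 4 lines run down to arm 2 in NEXN (from 45.9% to 33.9%), TNNT2, TPM1 and TTN, and up in NEBL (from 40.2% to 44.6%), MYL6 and MYL7. The MYL7 event drawn is an alternative 5′ splice site, other than the 3′ event that passed without the block.

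Best events of lists without a call included a 12-nucleotide exon of TEAD2, a partner of the YAP coactivator, at 40.9% ± 2.78 in arm 1 and 27.4% ± 9.54 in arm 2 (SD, n = 4 each; limma adjusted p = 0.336). The corresponding exons were at 4.95% against 27.2% for the growth factor receptor FGFR3 (adjusted p = 0.196), 52.0% against 46.8% for TERF1 (0.624), 84.0% against 88.7% for CNN2 (0.376), 93.0% against 96.1% for NCAM1 (0.755), 99.7% against 99.98% for APOA2 (0.709) and 95.0% against 68.0% for ESAM (0.698). The ESAM and FGFR3 exons had means of only 13.4 and 25.4 counts per library. PFKP, a glycolytic enzyme, had 1.90% against 0.800% (0.185). None of these limma tests over all 8 libraries, with or without the block, passed the threshold; TEAD2 passed without library 4 of arm 2 (adjusted p = 0.0390).

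Inclusion leaned to arm 1 among the 6 changed cassette exons, and 4 of the 6, or 66.7%, had a length divisible by 3. The share was 44.2% (6678 of 15126) among exons that did not change, and Fisher's exact test gave p = 0.416. The median length was 88.5 nucleotides for changed exons and 112 for the others. The 6 exons were all higher in arm 1 (two-sided exact binomial p = 0.0312, adjusted over the 5 kinds of event 0.156), so the lean did not pass the correction. Of the 48 exons of the blocked fit, 31, or 64.6%, had a length divisible by 3. Among the others the share was 44.1% (Fisher's exact p = 0.00528). Called and other exons were not matched on inclusion level or depth, which bear on the chance of a call. The excess may therefore reflect which exons can be called. In the blocked fit, 25 of 43 genes, or 58.1%, leaned to arm 1 (exact binomial adjusted p = 0.781).

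The authors' own test called far more events, most of them, mutually exclusive exons apart, with few reads. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 3517 of 89725 events passed, of which 987 had a mean of at least 10 junction counts per library. By kind, the authors' deposited table gave 2289 cassette exon, 462 mutually exclusive exon, 290 alternative 3′ and 216 alternative 5′ splice site events and 260 retained introns. Cassette exons in the authors' deposited table were split evenly, 1171 higher in arm 1 and 1088 in arm 2, and 76.6% of those called had a mean under 10 counts. Of the 10 events that limma called, 6 also passed in the authors' deposited table, and of the 68 blocked calls 30 did. For mutually exclusive exons, the FDR column of the authors' deposited table gave 94 events, of which 27.7% had a mean under 10 counts; of the 462 in the authors' deposited table by p-value 50.9% did.

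Junction read abundance per gene, taken from the deepest event of each gene, differed between the arms for genes of several tissues. ALDH1A1, a retinoic acid synthesis enzyme, had 786 ± 418 normalised counts in arm 1 and 120.0 ± 114 in arm 2, and RFX6, a transcription factor of gut and pancreatic endoderm, had 154 ± 58.2 against 15.4 ± 8.63. The ephrin receptor EPHA7 (387 ± 105 against 62.0 ± 13.3), the apolipoprotein APOA1 (541 ± 250 against 114 ± 71.3), the desmosomal cadherin DSC3 (200.2 ± 130 against 41.8 ± 27.4) and STRIP2 (230.3 ± 78.9 against 46.5 ± 9.73) were also higher in arm 1. ANGPT2, a ligand of the endothelial receptor TIE2, went the other way with 7.53 ± 7.65 against 96.7 ± 26.4. Higher in arm 2 as well were the myelin protein gene PMP22 (381 ± 162 against 1789 ± 556), the DNA end-joining factor XRCC4 (149.8 ± 19.1 against 530.0 ± 85.6) and GPM6B (67.1 ± 12.03 against 167 ± 26.1; SD, n = 4 each).

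Limma called 187 of 8859 genes at an adjusted p of 0.05, 122 higher in arm 1 and 65 higher in arm 2. The log2 differences were 3.51 ± 0.777 (SE) for ALDH1A1, 3.42 ± 0.514 for RFX6, 2.58 ± 0.266 for EPHA7, 2.41 ± 0.531 for APOA1, 2.32 ± 0.549 for DSC3 and 2.27 ± 0.291 for STRIP2, with limma adjusted p from 0.000245 for EPHA7 to 0.0412 for DSC3. They were -4.10 ± 0.508 for ANGPT2, -2.24 ± 0.2497 for PMP22, -1.82 ± 0.158 for XRCC4 and -1.28 ± 0.190 for GPM6B, with limma adjusted p from 4.04e-05 for XRCC4 to 0.00325 for GPM6B. IGFBP7 and ENSG00000250610, which lie together on chromosome 4 and may share reads, were -1.21 and -1.22 and are uncertain. With total count scaling 200 genes were called, 150 higher in arm 1 and 50 in arm 2. With the listed position as a replicate block 732 were called, 417 higher in arm 1 and 315 in arm 2, among them all 187. The count was 67 without library 1 of arm 1, 91 without library 3 of arm 1, and 69, 92 and 107 without library 2, 3 or 4 of arm 2. Of the 8 fits without a library, APOA1 lost its call in 6 (without library 1, 3 or 4 of arm 1, or 2, 3 or 4 of arm 2; adjusted p up to 0.0873). DSC3 lost it in 5 (without library 3 of arm 1 or any of arm 2; 0.126) and ALDH1A1 in 4 (without library 1 or 3 of arm 1, or 2 or 4 of arm 2; 0.102). The log2 difference of ALDH1A1 was 2.44 without library 2 of arm 2, 4.23 without library 3 of arm 2 and 2.77 in the blocked fit. That of APOA1 was 1.82 without library 2 of arm 2, and that of ANGPT2 -3.47 and -4.68 without library 1 or 4 of arm 1.

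Heart muscle and heart transcription factor genes that passed were all higher in arm 1. Of 44 sarcomere genes measured, 4 were higher in arm 1 and 0 in arm 2: TTN (log2 difference 0.81), NEBL (0.64), SORBS2 (0.98) and PDLIM5 (0.71). Of 44 cardiac and mesoderm transcription factors, 4 were higher in arm 1 and 0 in arm 2: GATA4 itself (1.95), TBX5 (0.91), EOMES (1.31) and ZFPM2 (0.98), which encodes the GATA4 partner FOG2. The mitochondria and energy list had 4 of 42 higher in arm 1 and 0 in arm 2, namely the fusion protein MFN1 (0.68), PDK1 (0.70), the coactivator PPARGC1A (0.66) and the muscle phosphofructokinase PFKM (0.53). Calcium handling genes were divided, with the calcium channel CACNA1D higher in arm 1 (1.504) and the calcium-binding protein CALU higher in arm 2 (-0.74) among 29. These list members were named after their values were seen.

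Limma calls adjusted over the list alone numbered 8 for the sarcomere list, 6 for the transcription factors, 7 and 1 (higher in arm 1 and in arm 2) for mitochondria and energy and 7 and 2 for calcium handling. With the replicate block by listed position they were 17 and 4, 7 and 1, 7 and 3, and 8 and 2 over all genes, so that the sarcomere list moved in both directions. Splicing regulators held 1 call among 124, PTBP2, a neuronal polypyrimidine tract-binding protein, at -0.62 (1 adjusted over the list alone, and 3 and 1 with the block). The cytoskeleton list held ADD3 (0.69) among 69, the WNT, BMP and TGF-beta list JAG1 (-0.66) among 53, and chromatin regulators HDAC9 (1.27) and DNMT3B (-0.71) among 84. Adjusted over the list alone these lists held 1, 2 and 2 calls, and with the block 5 and 3, 4 and 2, and 3 and 3. TTN-AS1, antisense to TTN, also had more reads in arm 1 (0.75, limma adjusted p = 0.0394), and their reads were not told apart.

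Markers of other cell types moved in different directions. Pluripotent cell markers had 2 of 9 higher in arm 1, TDGF1 (1.13) and EPCAM (0.87). Endoderm and hepatic markers had APOA1 higher in arm 1 (2.41) and the keratins KRT18 (-0.70) and KRT8 (-0.54) higher in arm 2, among 10, with a list median of 0.33. Smooth muscle, fibroblast and epicardial markers had 0 calls of 16 in limma over all genes and 1 adjusted over the list alone (COL1A1, -0.83), with a list median of -0.40. With the replicate block by listed position 6 were higher in arm 2. The endothelial (5 measured) and neural (5) lists had 0 calls, and 1 (ESAM, -1.10) and 0 adjusted over the list alone. For the pluripotent and endoderm lists the counts adjusted over the list alone were 2 and 0, and 2 and 2, and the blocked counts 2 and 1, and 4 and 2.

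**Figure D4:**
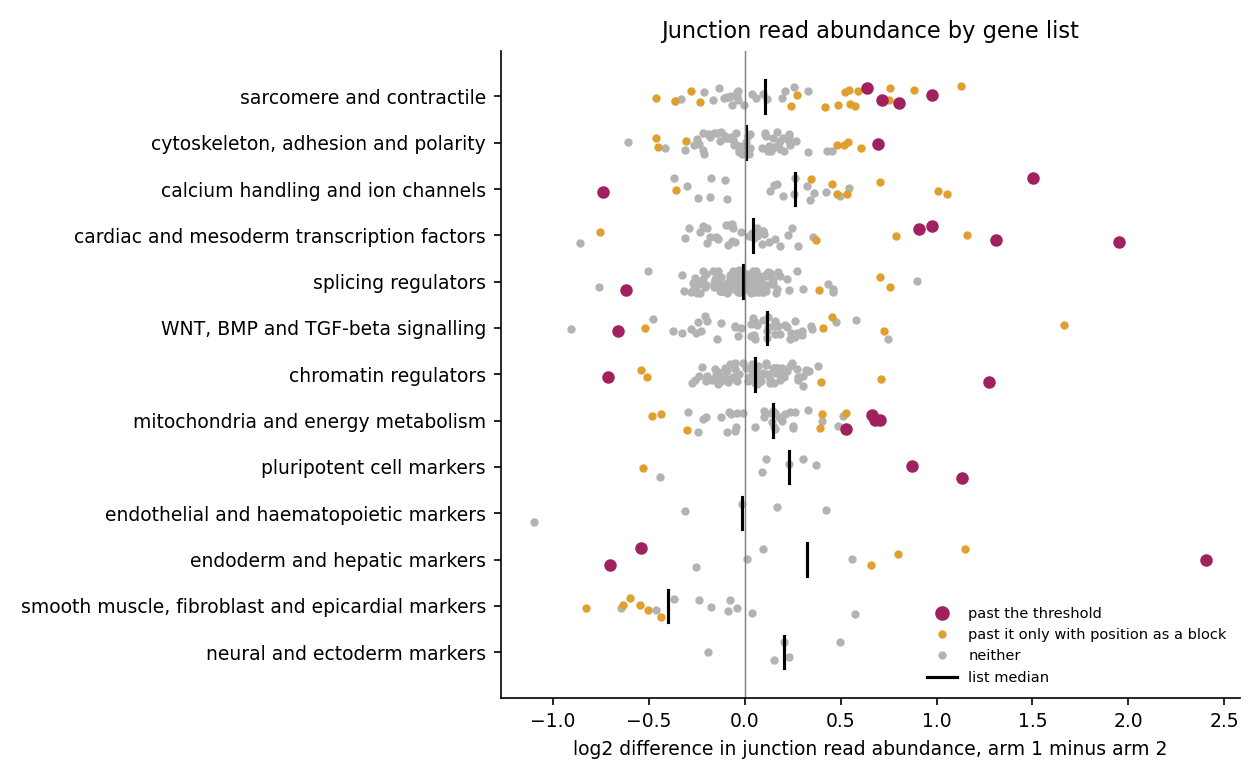
Log2 difference in junction read abundance, arm 1 minus arm 2 (x axis), of each measured gene of the 13 lists (y axis, with random vertical spacing), with the black bar for the list median. Purple points passed an adjusted p of 0.05 in limma and orange points only with the listed position as a block; the smooth muscle list has a median of -0.40 and the endoderm list of 0.33.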

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

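Of the tests weighed here, that on the matching of listed positions was chosen after the result was seen. So were those on the splits for splicing, except the one on cassette exons within positions. The block that this one uses was itself chosen after the data were seen.

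Single libraries stood far from the other 3 of their arm in 8 of 106 groups of 4 by Dixon's test, and chance alone gives about 5% of groups. SLU7 used the longer 5′ splice site form at 34.3% in library 3 of arm 2, against 27.3 to 28.3% in the others. FGFR3 exon inclusion was 53.3% in library 3 of arm 2, against 16.7 to 20.9%. The PFKP exon stood at 0.4% in library 2 of arm 2, against 0.9 to 1%. TERF1 was at 51.3% in library 1 of arm 2, against 44.8 to 45.8%. In library 4 of arm 1 the ESAM exon was at 80% and in the other 3 at 100%, with a mean of only 13.4 counts per library. APOA2 was at 99.9% in library 1 of arm 2 and at 100% in the other 3, a difference at the rounding of the levels. The overlapping genes ENSG00000250610 and IGFBP7 had 3384 and 2446 normalised counts in library 4 of arm 2, against 4468 to 4573 and 3170 to 3249.

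Setting listed positions 1 and 2 against 3 and 4 called 115 cassette exon events, several times the 6 called between the arms, which points to a structure of the samples. The other 2 splits by position called 7 and 0, and splits that follow no position up to 51. These counts do not decide on position. The other 2 splits by position mix the libraries that the first one parts. The split with 51 calls shares most of its libraries with the split that called 115. Chance cannot be excluded for the 6 calls, since 9 of the 35 splits of the libraries gave as many (highest other 115). A difference in depth is argued against as the whole cause: after thinning to equal totals the position split called 59 to 78 events, fewer than 115 but still at least 7.67 times as many as the arms, and a part played by depth stays open. A culture or preparation shared by the libraries at a position may underlie part of it, as the listed match had the highest summed correlation of abundance deviations of 24 matchings (1 as high), but no label names such a batch, and biological differences between cultures were not tested. Single libraries also stood out in the log ratios of deep cassette exon events. Their first principal component (20.7% of the variance) had a loading of 0.848 in library 2 of arm 1 and 0.225 in library 2 of arm 2. The second (19.4%) had 0.793 in library 1 of arm 2 and 0.343 in library 1 of arm 1. Single deviating libraries therefore cannot be told apart from an effect of position. Swapping arms within positions allows only 8 splits, too few for a share under 5%, with 49 real calls and at most 8 in another.

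Chance cannot be excluded either for alternative 3′ splice sites, where 4 of 35 splits gave as many (3 real calls, highest other 6), or for alternative 5′ splice sites, where 8 did (1 and 12). Mutually exclusive exons and retained introns had 0 real calls, so that all 35 splits gave as many by definition and nothing was tested; the highest other counts were 40 and 27. For abundance chance is argued against, with 1 of 35 splits as large, the real one itself (187 real calls, highest other 5). That is the smallest share these splits can give, so chance is not excluded. Within positions, 8 splits are too few for a share under 5%. The real and highest other counts were 9 and 39 for mutually exclusive exons, 2 and 6 for retained introns, 4 and 1 for alternative 3′ splice sites, 4 and 1 for alternative 5′ splice sites, and 732 and 0 for abundance. The 39 is several times the real count and points to a structure of the samples.

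The authors' p-values called mostly events with few reads, though of the 94 mutually exclusive exon events past their deposited FDR 27.7% had a mean under 10 counts. Levels did not overlap between the arms in 6.25% of the authors' 608 calls with 2 to 10 counts and in 20% of 605 calls with 20 or more. Over all events the shares were 1.18% of 8155 and 1.38% of 62375, a ratio of 0.855. Both shares over all events lie under the 2.86% that chance gives, so they do not decide on larger differences in weakly expressed genes. The 6.25% among the authors' calls lies above it. Those calls were picked for a difference between the arms, so their share does not decide on sampling noise at low counts. The 6.25% met the limit set beforehand for sampling noise. The ratio of 0.855 met the limit set against larger differences in weakly expressed genes. For the reasons given, neither decides, and both explanations stay open.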

How the results depend on the processing

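The block by listed position and the depth limit on the authors' calls were chosen after the data were seen; the cause of each change below was not tested. GATA4 had a log2 difference of 1.86 to 2.10 with other scalings and without each library; its permutation p is the smallest possible in each, which says nothing of stability. With the listed position as a replicate block, counts moved to 49 for cassette exons, 9 for mutually exclusive exons, 4 for alternative 5′ splice sites, 2 for retained introns and 732 for abundance, 1 gene list passed in place of 0, and frame preservation passed (64.6%, Fisher's exact p = 0.00528); alternative 3′ splice sites went from 3 to 4 and no direction passed. The frame test did not match exons on inclusion level or depth. Without weights limma called 0 cassette exons, 1 mutually exclusive exon event, 0 alternative 3′ and 0 alternative 5′ splice sites. Without a count filter, where more events are tested, it called 1 cassette exon and 0 alternative 3′ splice sites; with a pseudocount of 2 it called 1 cassette exon; with a 10-point minimum 0 alternative 3′ splice sites; quasi-binomial regression called 0 alternative 5′ splice sites. The authors' p-values gave 2289 cassette exons, 462 mutually exclusive exons (94 by the deposited FDR), 290 alternative 3′ and 216 alternative 5′ splice sites and 260 retained introns, and with a mean of at least 10 counts 535, 227, 81, 55 and 89. Leaving out a library gave 11 to 27 cassette exons, 0 to 2 mutually exclusive exons, 1 to 6 alternative 3′ and 0 to 3 alternative 5′ splice sites and 67 to 215 abundance genes. Mutually exclusive exons rose to 2 without library 4 of arm 1; alternative 5′ splice sites fell to 0 without library 1, 2 or 3 of arm 1 or 3 or 4 of arm 2 and rose to 3 without library 2 of arm 2. Scaling, the sum over events, a lower count minimum and leaving out genes that share coordinates left abundance at 185 to 222 genes. The 12 named abundance genes kept their calls under the other scaling, the sum and the block, and lost them in 15 of 96 fits without a library; named events lost theirs in 18 such fits, and others gained one in 33. The count models planned only for tables with a column per library were not run; the quasi-binomial regression used the counts of each library, and sequence motifs were not run for want of a matching genome. Of simulated cassette exons with a log2 change of 1, the limma test recovered 8.5%.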

Other observations

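The tests on these patterns were set before their results were seen; the genes named below were chosen after their values were seen.

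Further genes were called in abundance. ANGPT1, a ligand that activates the receptor TIE2, had 123 ± 52.1 normalised counts in arm 1 and 50.4 ± 7.57 in arm 2 (log2 difference 1.18), opposite in sign to ANGPT2. VEGFC, a lymphatic growth factor (1.72), BMP5 (1.84), WNT2 (1.69) and the adhesion molecule VCAM1 (2.10) were higher in arm 1, and the growth factor PDGFA was lower (-0.97). The formin FHOD3 (528 ± 63.5 against 206 ± 36.2; 1.35), MYOZ2 (1.08) and the nuclear receptor ESRRG (1.15) were also higher in arm 1. So were the mitochondrial calcium uniporter MCU (1.31) and the transhydrogenase NNT (1.41). Higher in arm 2 were asparagine synthetase ASNS (475 ± 88.0 against 991 ± 293; -1.02), PCK2 (-1.17) and SHMT2 (-0.83). So were the glutamine transporter SLC1A5 (-0.86), the tRNA synthetases GARS (-0.80) and MARS (-0.62) and the cyclin CCND3 (-1.54). In all of these, limma with Benjamini-Hochberg adjustment gave an adjusted p under 0.05 (SD, n = 4 each).

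APOA1 (541 ± 250 against 114 ± 71.3 normalised counts), HABP2 (591 ± 260.3 against 158 ± 85.5; log2 2.06), RFX6 and ALDH1A1 were higher in arm 1, while the fixed endoderm and hepatic list held 1 call higher in arm 1 and 2 higher in arm 2. A lower share of cardiac cells in arm 1 is argued against only in the form that raises the markers of every other type. The smooth muscle, fibroblast and epicardial list had a median of -0.40. The sarcomere list had one of 0.11, with 25 of 44 genes higher in arm 1. The limit set needed just a single other list to go down, and changes within cells could move either list. Other shifts in cell shares therefore stay open. Fewer endoderm-like cells in arm 2 may account for these genes, but this cannot be told apart from a change within cells: the 10 measured endoderm and hepatic markers had a median of 0.33, 7 of them higher in arm 1, while KRT8 and KRT18, which cardiac progenitors may also express, were lower in arm 1. The treatment itself stays among the open explanations, as untested.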
